A study of Borreliella burgdorferi with 3 samples.

How the data were processed

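RNA sequencing measured transcripts of Borreliella burgdorferi strain B31 in 1 library from cells and 2 libraries from outer membrane vesicles (OMVs). Per the labels' protocols, cells were held for 3 h at 34 °C in medium with vesicle-depleted serum. The supernatant was passed through a 0.22 µm filter and concentrated, and OMVs were recovered either by ultracentrifugation (UC) at 100000 x g or on a qEV size-exclusion column. RNA was extracted with a kit that keeps small RNA, with an added step that removes ribosomal RNA, and sequenced from NEBNext Ultra libraries, per the labels. The ribosomal depletion is stated for the whole series, and only the cell library also carries it in its source name. For each OMV library, the title and the isolation label name 1 method and the description, which is also the column name, names the other. Which method made which library is therefore not settled here. The libraries are called the OMV library named UC and the OMV library named qEV, after the column names, and both were placed in a single OMV group.

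The authors deposited raw counts of reads per annotated gene, not normalized, in a single table with 1 column per library. Reads were aligned with Bowtie, per the submitters' processing notes, which give no version. The genome build, the annotation version, the strand setting of the counting and the treatment of reads with several hits are not given in the sources used here. Blank cells were read as 0 counts, since the smallest value listed was 1. The table held 1379 genes, of which 1342 were protein-coding, 5 were rRNA genes and 32 were tRNA genes, on the chromosome and 21 plasmids. Some symbols stood on several lines of the same replicon (40 lines repeated a symbol already listed there), and these lines were kept apart. A value given for such a symbol is that of a single line. Genes of the cp32 plasmids, of lp56 and of the erp, mlp and bdr families have near-identical copies, so their counts are uncertain wherever the counting split reads between copies.

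Total counts were 1605360 in the cell library, 2321584 in the OMV library named UC and 5379911 in the OMV library named qEV. Counts were tested in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood test (glmQLFit and glmQLFTest) on all 3 libraries, TMM normalization, the filterByExpr filter with its minimum count of 10, and Benjamini-Hochberg adjustment at 0.05. The filter kept 1226 genes, of which 1189 were protein-coding, and left out 153. TMM factors were 1.49 for the cell library, 0.832 for the OMV library named UC and 0.807 for the OMV library named qEV. The fit had 1 residual degree of freedom, taken from the 2 OMV libraries, so the single cell library was assumed to vary like them. A further 5.41 prior degrees of freedom came from sharing the spread over genes. The common dispersion was 0.171, a biological coefficient of variation of 0.414. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Scaled CPM values used library sizes multiplied by TMM factors, and log2 CPM used a prior count of 2. Fold changes are OMV over cell.

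The test was checked on 10 simulated sets of the 1226 genes for the comparison of OMVs with cells, with 200 genes changed. It recovered 89.5% of genes changed 16-fold and 27% of genes changed 4-fold, and 3.56% of its calls were false. All simulated libraries were drawn from the dispersion fitted here, with as many genes raised as lowered. The check thus takes as given that the cell library varies like the OMV libraries. It also leaves out an uneven shift such as that of the tRNAs, so its share of false calls may not hold for the real libraries. Intervals on shares and on ratios of counts are exact binomial 95% intervals. They cover counting error only, since reads without molecular identifiers are not independent molecules. Where the cell library had 0 counts, the fold was the mean scaled CPM of the 2 OMV libraries over a floor of 3 cell counts. Such a fold is not a lower bound for either OMV library alone. Where the cell library had 1 to 3 counts, the ratio of pooled OMV to cell counts is given with its interval.

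The genes named, the gene lists, the design and most alternatives were chosen before the data were examined. The named genes were the 10 with the largest and the 10 with the smallest log2 fold change among those past the threshold with the same direction in both OMV libraries, the 3 members of each list with the highest mean CPM, the 5 genes with the most counts in each library, and the 6 genes with the largest ratio in each direction between the OMV libraries among those with at least 50 counts. The 10 protein-coding genes with the largest increase among those past the threshold were added after the values were seen, because the 10 largest increases under that rule were all tRNAs. The lists were outer surface lipoproteins on plasmids, outer membrane proteins on the chromosome, flagella and chemotaxis, ribosomal proteins, glycolysis, chaperones and proteases, regulators of host adaptation, uptake of oligopeptides, sugars and glycerol, RNA polymerase and DNA replication, genes of the cp32 family and lp56, the erp, mlp and bdr families, and stable RNAs. For each list except the stable RNAs, the median over its members of the mean log2 CPM difference was placed among 10000 random lists of protein-coding genes of the same size, matched on mean expression. These percentiles describe the 3 libraries and are not tests of the condition. Random lists were drawn gene by gene, while several lists hold runs of neighbouring genes. Neighbouring chromosomal genes had related fold changes, so percentiles of such lists may be too extreme. The list members ospD, lptD and besB were not analysed here.

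Genes at least 2-fold apart in the same direction in both OMV libraries were counted beside 100 simulations with no effect that shared the single cell library. The simulated cell library was drawn from the same fitted dispersion as the OMV libraries. Enrichment of replicons among called protein-coding genes used two-sided Fisher's exact tests over the protein-coding genes tested, 4 in all, with Benjamini-Hochberg adjustment. The alternatives were DESeq2 size factors, total counts without TMM, TMM from protein-coding or from chromosomal protein-coding genes, other count filters, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), omission of the cp32 family and lp56, other prior counts and omission of each OMV library. The blank medium control that the labels mention was not analysed here.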

Results

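The series recorded RNA from Borreliella burgdorferi B31, a spirochaete that causes Lyme disease, and from the outer membrane vesicles (OMVs) it released into culture medium. There were 1 cell library and 2 OMV libraries, with total counts from 1605360 to 5379911 per library. The comparison asks, after the title of the series, whether transcripts were distributed unequally between the bacteria and their OMVs. Counts above 0 were found for 1300 genes in the cell library, 1334 in the OMV library named UC and 1352 in the OMV library named qEV, out of 1379 in the table. The labels conflict on which isolation method made which OMV library, so those names are column names only. Nothing in the labels says that the OMV libraries came from separate cultures. The p-values thus rest only on the spread between these 2 libraries, much of it shared over genes. That spread was in part that between isolation methods. The cell side had no replicate.

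Transfer RNA, which brings amino acids to the ribosome, made up 56.8% of counts in the OMV library named UC (95% exact binomial interval 56.7 to 56.9) and 31.4% in the one named qEV (31.3 to 31.4). In the cell library it made up 0.0183% (0.0163 to 0.0205), or 294 counts over 32 tRNA genes. The summed tRNA count, scaled by library, was 5561-fold (4960.3 to 6256) and 3168-fold (2826 to 3563) higher in the OMV libraries named UC and qEV than in cells. All 32 tRNA genes were higher in the OMV libraries in edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p from 0.0131 to 0.0409. BB_t28, a methionine tRNA, held 26.7% of tRNA counts in the OMV library named UC and 18.4% in the one named qEV. BB_t22, listed without its amino acid, held 14.3% and 8.61%.

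The 10 largest increases named by the fixed rule were all tRNAs. For those with 0 counts in cells, the mean of the OMV libraries was set against the floor of 3 cell counts. That mean was 52246-fold the floor for BB_t22, 24590.2-fold for tRNA-Trp-1 and 9318-fold for BB_t21, an arginine tRNA. The values were 5254-fold for tRNA-Phe-2, 4454-fold for BB_t26 (arginine), 1973-fold for tRNA-Thr-2 and 1289-fold for BB_t33 (threonine). As means, they are not lower bounds for each library. Scaled CPM in the libraries named UC and qEV was 97465 and 33523 for BB_t22, but 808 and 4139 for tRNA-Thr-2. With 1 cell count each, tRNA-Lys-2 had a ratio of 33392 (5993 to 1.32e+06) and tRNA-Gln-1 a ratio of 20230.3 (3631 to 799070). tRNA-Ala-1, with 4 cell counts, had a log2 fold change of 14.43 ± 2.17 (SE, n = 2 OMV libraries against 1, edgeR adjusted p = 0.0151). Cell counts were low for the whole class, with 8 tRNA genes at 0, 11 at 1 to 3 and a highest count of 68, while the lowest tRNA count in an OMV library was 791.

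Ribosomal RNA made up 77.5% of counts in cells (77.4 to 77.5), 30.0% in the OMV library named UC (30.0 to 30.1) and 60.9% in the one named qEV (60.8 to 60.9). None of the 5 rRNA genes passed edgeR's test, and 0 had an unadjusted p under 0.05 in edgeR, DESeq2 or limma-voom. The log2 fold changes were 1.21 ± 1.84 for 16S rRNA, -0.61 ± 1.64 for the 23S gene rrlB and -0.41 ± 1.62 for the 23S gene rrlA (SE, n = 2 against 1), and the last was 0.05 with TMM from chromosomal genes. The ratio of 16S to 23S counts was 0.275 in cells and 1.00 and 0.872 in the OMV libraries named UC and qEV. Protein-coding genes made up 22.5%, 13.2% and 7.74% of counts in cells and in the OMV libraries named UC and qEV. Only the cell library carries the ribosomal depletion in its source name. Unequal depletion could therefore contribute to these shares and to the ratio of 16S to 23S, which was not tested. The 5 genes with the most counts in cells were both 23S genes, 16S, and ospA and ospB, which encode the major outer surface lipoproteins of the cultured spirochaete. In both OMV libraries they were 16S, both 23S genes, BB_t28 and BB_t22.

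**Figure D1:**
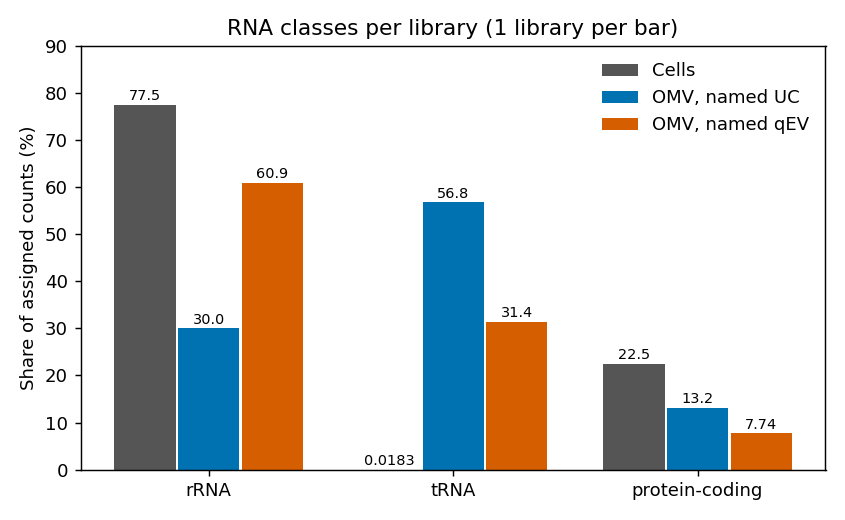
Share of all assigned counts (%, vertical axis) in rRNA, tRNA and protein-coding genes, with 1 bar per library. The tRNA share was 0.0183% in cells against 56.8% and 31.4% in the OMV libraries named UC and qEV.

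Among protein-coding genes, plasmid genes made up nearly all that were higher in the OMV libraries, and chromosomal genes nearly all that were lower. Of 401 plasmid genes tested, 32 were higher and 1 was lower (BB_G24, on lp28-2), with a median log2 fold change of 1.26. Of 788 chromosomal genes, 3 were higher and 30 were lower, with a median of -0.47. The 3 higher were mreC, whose product takes part in cell shape, with a log2 fold change of 3.86 ± 0.88 (edgeR adjusted p = 0.0494), BB_0412, a membrane protein, at 3.45 ± 0.70 (0.0390), and trpS, a tryptophan tRNA ligase, at 2.84 ± 0.62 (0.0453), all chosen after their values were seen. Plasmid genes were over-represented among the protein-coding genes called higher (32 of 401 against 3 of 788, odds ratio 22.6, Fisher's exact p = 7.23e-13, adjusted 2.89e-12). Chromosomal genes were over-represented among those called lower (30 of 788 against 1 of 401, odds ratio 15.8, Fisher's exact p = 6.09e-05, adjusted 8.12e-05). Genes are not independent replicates, and these tests describe the calls in these 3 libraries. A call lower also needs enough counts in cells. The cp32 family held 5205 cell counts over 270 genes, against 251179 protein-coding cell counts over 797 genes on the chromosome. The odds ratio of 15.8 may thus in part restate abundance in cells.

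Over all 1226 genes, edgeR's quasi-likelihood test called 67 higher in the OMV libraries, 32 tRNA and 35 protein-coding, and 31 lower, so that 68.4% of calls were higher. An unadjusted p under 0.05 was found for 399 genes. The split depended on the scaling. With total counts alone, 95 were higher and 288 lower (24.8% higher) and the log2 fold change shifted by a median of -0.86 over genes. With TMM from chromosomal genes, 146 were higher and 26 lower (84.9% higher) with a shift of 0.45. The median of plasmid genes stayed above 0 in both (0.41 and 1.71), as did that of lp54 genes (2.52 and 3.81), while that of chromosomal protein-coding genes was -1.33 with total counts and -0.012 with TMM from those genes. The shift was 0.12 with TMM from protein-coding genes and 0.20 without the cp32 family and lp56. Genes at least 2-fold higher in both OMV libraries numbered 261 and at least 2-fold lower 216, against a mean of 65.6 (highest 81) and 43.7 (highest 61) in 100 simulations with no effect.

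Of the plasmids, lp54, which carries ospA, ospB and the decorin-binding proteins, had the highest median log2 fold change, 3.37 over 52 genes, with medians of 3.86 and 1.88 in the libraries named UC and qEV. On lp54, 46 genes had a positive and 6 a negative fold change, and 6 passed the test, all higher: BB_A08, BB_A09, BB_A43, BB_A46, BB_A73 and cspA. The rate of calls on lp54 exceeded that of other protein-coding genes (6 of 52 against 29 of 1137, odds ratio 4.97, Fisher's exact p = 0.00319, adjusted 0.00319). The plasmids other than lp54 also stood above the rest, here lp54 and the chromosome together (26 of 349 against 9 of 840, odds ratio 7.42, Fisher's exact p = 3.12e-08, adjusted 6.24e-08). Their median was 1.09. The genes set against lp54 included those of the other plasmids, so the odds ratios of 4.97 and 7.42 do not rank lp54 against other plasmids. Medians were 1.72 for lp28-2, 1.55 for lp36, 1.40 for lp17, 1.22 for lp56, 1.00 for lp28-3, 0.94 for cp26 and 0.92 for the cp32 family. For lp28-1, where 3 of 6 genes had 1 to 3 cell counts, the median was 2.12, or 1.61 with those genes at the floor. On cp26, the 6 genes higher in the OMV libraries included BB_B23, a guanine and xanthine permease, at 4.25 ± 0.74 (SE, edgeR adjusted p = 0.0220), and BB_B27, a lipoprotein, at 3.94 ± 0.81 (0.0404), both chosen after their values were seen.

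As a share of protein-coding counts, all plasmids made up 30.5% in cells (exact binomial interval 30.4 to 30.7), 56.2% in the OMV library named UC (56.1 to 56.4) and 42.7% in the one named qEV (42.6 to 42.9). The share of lp54 was 21.5%, 45.6% and 20.5%. Without ospA and ospB, the share of lp54 was 2.17% in cells, 22.1% in the OMV library named UC and 8.45% in the one named qEV, and the pair itself held 19.3%, 23.6% and 12.0%. Of all counts, which include the tRNAs and rRNAs, plasmids made up 6.87%, 7.40% and 3.31%, and lp54 4.84%, 6.003% and 1.58%. The OMV share of lp54 in all counts thus depended on the library, with a mean of 3.79% over both, 6.003% without the one named qEV and 1.58% without the one named UC.

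**Figure D2:**
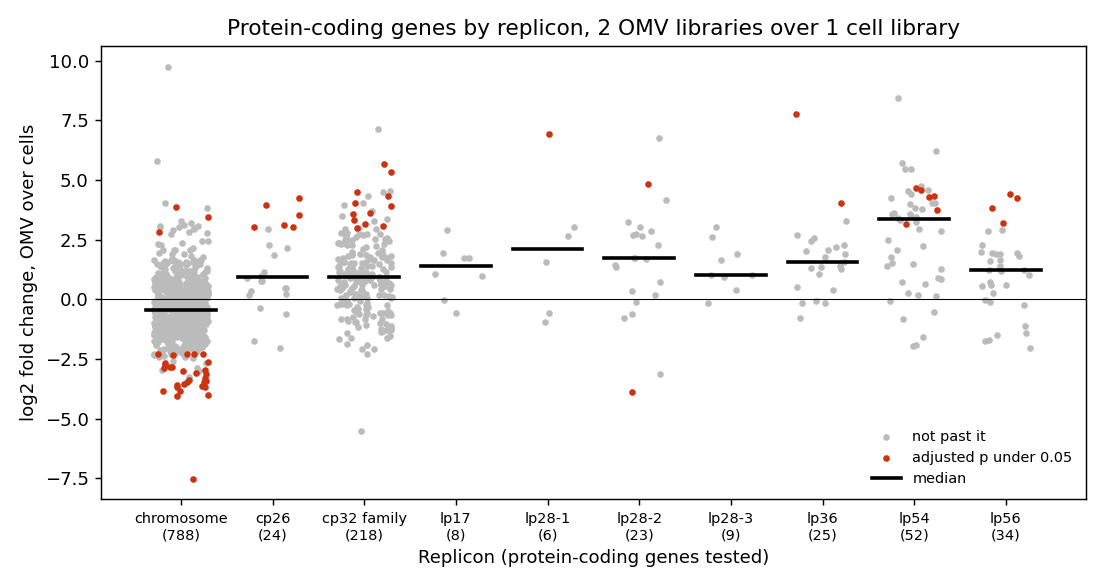
Log2 fold change of OMV over cells (vertical axis) for each protein-coding gene tested, grouped by replicon with the number of genes in parentheses, with medians as bars and genes past the edgeR threshold in red. The median was -0.47 on the chromosome and 3.37 on lp54, and lp21 and lp28-4, with 1 gene tested each, are not drawn.

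Among protein-coding genes past the threshold, the 10 with the largest increase all lay on plasmids, and this group was chosen after the values were seen. The lp54 genes BB_A49, at 8.45, and BB_A69, at 5.72, did not pass (edgeR adjusted p = 0.0670 and 0.0700). Of the 10, most are annotated as hypothetical proteins. BB_K35 on lp36 had 4 counts in cells, 873 in the OMV library named UC and 1306 in the one named qEV, a log2 fold change of 7.78 ± 0.90 (SE, n = 2 against 1, edgeR adjusted p = 0.0131). BB_F17, a putative transmembrane protein on lp28-1 with 1 cell count, had a ratio of 131 (23.4 to 5202). The surface lipoprotein genes mlpG and mlpI, on cp32 plasmids, had log2 fold changes of 5.69 ± 0.76 and 5.36 ± 0.75 (edgeR adjusted p = 0.0136 for each). BB_G29 on lp28-2 was at 4.84 ± 0.70 (0.0144), and the lp54 genes BB_A08 and BB_A09 were at 4.65 ± 0.72 (0.0169) and 4.60 ± 0.99 (0.0444). BB_S19, with 2 cell counts, had a ratio of 25.01 (6.79 to 209). BB_Q07, a plasmid partition protein on lp56, was at 4.43 ± 0.67 (0.0153) and BB_O22 at 4.34 ± 0.68 (0.0171). Genes on cp32 plasmids and lp56 have near-identical copies, and their values are uncertain where reads were split.

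The 10 largest decreases named by the fixed rule were in 9 chromosomal genes and 1 gene of lp28-2. bmpD, a basic membrane lipoprotein, had 1396 counts in cells against 54 and 180 in the OMV libraries named UC and qEV, a log2 fold change of -4.06 ± 0.56 (SE, n = 2 against 1, edgeR adjusted p = 0.0136). BB_0243, the glycerol-3-phosphate dehydrogenase, was at -3.69 ± 0.63 (0.0217), and its neighbour BB_0242 at -3.83 ± 0.66 (0.0220). The aminopeptidase BB_0366 was at -3.63 ± 0.59 (0.0189), the D-alanine ligase BB_0200, which makes a cell wall precursor, at -3.66 ± 0.61 (0.0215), and lnt, which acylates lipoproteins, at -3.86 ± 0.66 (0.0220). BB_0143, a membrane protein insertion factor, was at -4.02 ± 0.58 (0.0144), BB_0062, an rRNA methyltransferase, at -3.57 ± 0.73 (0.0390) and BB_G24 at -3.90 ± 0.75 (0.0295). BB_0305 had 19 counts in cells and 0 in both OMV libraries (edgeR adjusted p = 0.0453), which gave no spread of their own for this gene. Against a floor of 3 counts over both OMV libraries, BB_0305 was 16.6-fold lower. The exact interval of its ratio of OMV to cell counts reached up to 0.0818.

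Of 17 outer surface lipoproteins on plasmids, edgeR called 2 higher and 0 lower, and the same 2 passed when adjusted over the list alone. DESeq2 and limma-voom each called 4 higher and 0 lower, and 6, 7 and 5 had an unadjusted p under 0.05 in edgeR, DESeq2 and limma-voom. They were cspA, which binds complement factor H, at 4.34 ± 0.88 (SE, edgeR adjusted p = 0.0390), and BB_A73, a P35 antigen, at 3.76 ± 0.70 (0.0293). The most abundant members did not pass. The values were 0.16 ± 1.14 for ospB (-0.69 with total counts), -0.82 ± 1.02 for ospA, which the table lists as a pseudogene, and -1.91 ± 0.70 for lp6.6 (edgeR adjusted p = 0.119). The list's median difference was 0.18 (72.5th percentile of random lists, but 0.11th of lists of plasmid genes only, a comparison added after the data were seen), and -0.66 with total counts. It was 1.11 in the library named UC and 0.11 in the one named qEV, and the percentile was 98.0 on the library named UC alone. Of 18 chromosomal genes on the list named outer membrane proteins, edgeR called 1 lower (bmpD) and 0 higher, with a median of -0.50 (21.6th percentile). Adjusted over the list alone, 2 were lower (bmpD and BB_0141, listed as besA). Where the product of each listed gene lies was not checked here. DESeq2 and limma-voom each called 2 lower and 0 higher, and 6, 4 and 5 had an unadjusted p under 0.05 in edgeR, DESeq2 and limma-voom. The porin p66 was at -1.77 ± 0.61 (edgeR adjusted p = 0.106), BB_0795 at -1.18 ± 0.54 (0.182) and P13 (BB_0034) at -0.17 ± 0.64 (0.873), which was 0.28 with TMM from chromosomal genes.

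Central metabolism and gene expression lists lay at low values. All 11 glycolysis genes had negative fold changes, and 2 were lower in edgeR's test, pyk (pyruvate kinase) at -2.85 ± 0.62 (adjusted p = 0.0457) and BB_0020 (a phosphofructokinase) at -2.28 ± 0.51 (0.0482). Adjusted over the list alone, 4 were lower, with tpiA and BB_0087 added. The median was -1.49 (0.7th percentile), with fbaA at -1.48 ± 0.57, gap at -1.17 ± 0.58 and pgk at -0.86 ± 0.58. Of 9 genes of RNA polymerase and DNA replication, 1 was lower, the polymerase clamp gene dnaN at -3.13 ± 0.64 (edgeR adjusted p = 0.0393), and 2 when adjusted over the list alone (dnaN and gyrA). The values were -1.54 ± 0.64 for rpoC, -1.70 ± 0.60 for rpoB and -2.07 ± 0.58 for gyrA (edgeR adjusted p = 0.153, 0.110 and 0.0700), and the median was -1.57 (0.325th percentile, 3.66th on the library named UC alone). Of 35 ribosomal proteins, edgeR called 1 lower, rpmJ at -2.90 ± 0.66 (adjusted p = 0.0494), and 0 when adjusted over the list alone, while DESeq2 called 1 lower and limma-voom 5 lower. An unadjusted p under 0.05 was found for 15, 9 and 15 in edgeR, DESeq2 and limma-voom. Their median was -1.15 (0.065th percentile). Many of the ribosomal protein genes are neighbours on the chromosome, unlike the genes of a random list, so this percentile may be too extreme. The most abundant ribosomal proteins were at 0.21 ± 0.65 for rpsG (-0.65 with total counts), -0.14 ± 0.68 for rplC and -0.29 ± 0.57 for rplB, the last 2 at 0.30 and 0.16 with TMM from chromosomal genes. Against random lists of chromosomal genes only, a comparison added after the data were seen, the percentiles were 2.62 for glycolysis, 0.765 for RNA polymerase and DNA replication, 1.03 for ribosomal proteins, 29.9 for chaperones and proteases and 51.3 for outer membrane proteins.

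None of the 40 genes of flagella and chemotaxis passed edgeR's test, also adjusted over the list alone, with 8 at an unadjusted p under 0.05, while DESeq2 called 1 lower and limma-voom 2 lower. Their median was -0.71 (1.09th percentile, and 12.6th among chromosomal lists only), or -0.72 with the gene of 1 cell count, fliQ, at the floor. The flagellin gene BB_0147 was at -2.67 ± 0.68 (edgeR adjusted p = 0.0609), the hook gene flgE (BB_0283) at -0.81 ± 0.58 and fliD (BB_0149) at -1.26 ± 0.55. Of 14 chaperones and proteases, 2 were lower over all genes and when adjusted over the list alone, the periplasmic protease BB_0104 at -2.34 ± 0.53 (edgeR adjusted p = 0.0482) and the chaperone htpG (BB_0560) at -2.31 ± 0.53 (0.0494). The list's median was -0.70 (10.9th percentile), with groL at -2.08 ± 0.68, lon at -0.83 ± 0.56 and clpP at 0.47 ± 0.76, which was -0.38 with total counts. Both lon and clpP stood on several lines, and the value given is that of the line with the highest mean CPM. Of 18 genes of oligopeptide, sugar and glycerol uptake, 3 were lower: the glycerol channel BB_0240 at -2.65 ± 0.58 (edgeR adjusted p = 0.0453), the glycerol kinase glpK at -3.43 ± 0.64 (0.0293) and BB_0243. Adjusted over the list alone, 5 were lower, with the chitobiose transporter gene BB_B04 and BB_0328 added. Its median was -0.44 (26.0th percentile), and 0.0025 with TMM from chromosomal genes, and BB_B16 was at -0.60 ± 0.58. None of 11 regulators of host adaptation passed, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 in edgeR, DESeq2 or limma-voom. The regulators' median was -0.57 (20.3th percentile), with BB_0712 at 0.66 ± 0.71 and BB_0420 at 0.05 ± 0.54, both negative with total counts (-0.20 and -0.82), and BB_0355 at -0.57 ± 0.53.

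Of 252 genes of the cp32 family and lp56, edgeR called 16 higher and 0 lower, DESeq2 25 higher and 0 lower, and limma-voom 18 higher and 1 lower, with 78, 66 and 70 at an unadjusted p under 0.05. In edgeR, 9 were higher when adjusted over the list alone. Their median was 0.84 (100th percentile among all protein-coding lists, but 5.66th among plasmid lists only), or 1.00 with 17 genes of 3 or fewer cell counts at the floor. These 252 genes are most of the 401 plasmid genes tested. Random plasmid lists therefore held largely the same genes, and the 5.66th percentile is no comparison with other plasmid genes. Of 28 genes of the erp, mlp and bdr families, which encode surface lipoproteins and repeat proteins of these plasmids, 3 were higher and 0 lower in edgeR: mlpG, mlpI and bdrP, the last at 3.59 ± 0.64 (adjusted p = 0.0249). DESeq2 and limma-voom each called 5 higher and 0 lower, and 15, 13 and 14 had an unadjusted p under 0.05 in edgeR, DESeq2 and limma-voom. Adjusted over the list alone, 7 were higher, and 25 members had positive fold changes. The median was 1.61 (100th percentile, or 80.7th among plasmid lists only), or 1.75 with 2 genes at the floor. erpB was at 0.91 ± 0.77 and erpO at 0.24 ± 0.57, the latter at -0.62 with total counts. Counting may have split reads between copies in all these families.

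**Figure D3:**
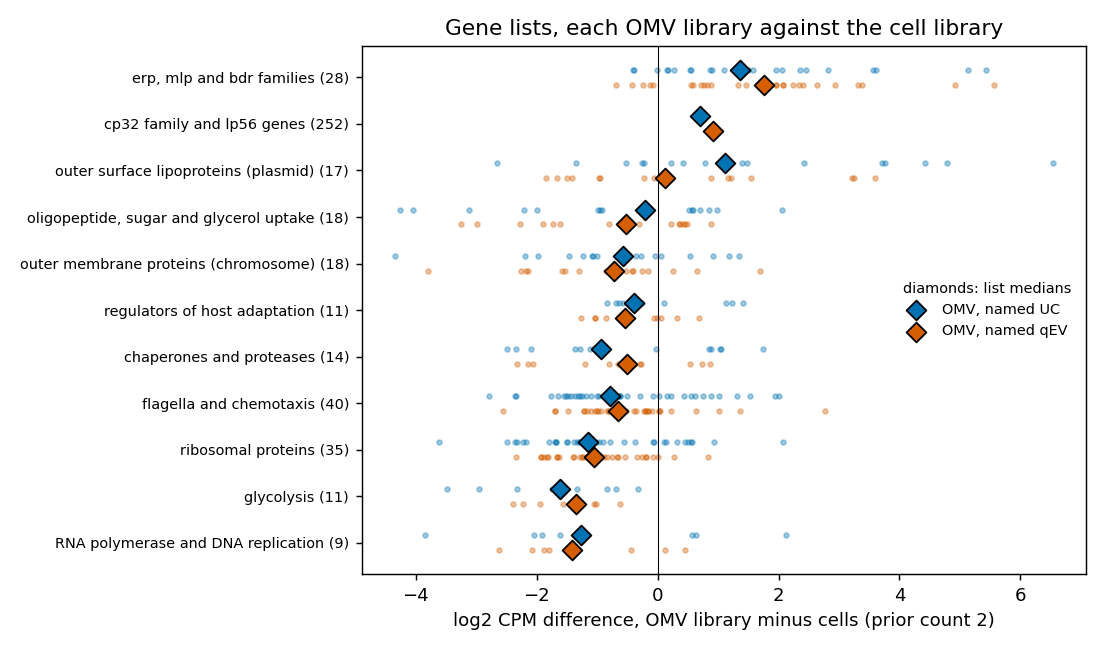
Log2 CPM difference of each OMV library from the cell library (horizontal axis) for the gene lists, with the number of genes tested in parentheses, members as dots and list medians as diamonds, and medians only for the cp32 family and lp56. Medians over both libraries ran from -1.57 for RNA polymerase and DNA replication to 1.61 for the erp, mlp and bdr families, those of the outer surface lipoproteins and of uptake changing sign under another scaling.

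Many lp54 genes were higher in the OMV library named UC than in the one named qEV. With at least 50 counts over both, 40 of 48 lp54 genes were at least 2-fold higher in the library named UC, with a median ratio of 3.40, while the median log2 difference was 0.00 over 706 chromosomal genes and 0.18 over the 32 tRNAs. Of the 6 largest ratios in that direction, 5 were lp54 genes. The ratio of UC to qEV was 24.3 (exact interval 21.95 to 27.0) for BB_A49, 14.9 (7.03 to 36.3) for BB_A58, 12.5 (9.75 to 16.2) for dbpA, which binds decorin, 12.3 (11.2 to 13.6) for the phage terminase BB_A31 and 9.96 (9.21 to 10.8) for the surface protein BB_A69. The sixth was BB_0172, a protein with a von Willebrand factor domain, at 14.1 (12.4 to 15.95). In the other direction the ratio of qEV to UC was 5.78 (2.13 to 22.02) for the endonuclease BB_0745, 5.16 (2.09 to 16.5) for BB_N33, 5.13 (4.87 to 5.40) for tRNA-Thr-2, 4.81 (1.94 to 15.4) for ftsY, 4.70 (2.17 to 12.1) for lspA and 4.48 (2.53 to 8.65) for BB_0130.

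Of 1024 genes with at least 50 counts, 79 were at least 2-fold higher in the library named qEV and 146 in the one named UC. Across 1226 genes, which are not independent replicates, log2 CPM of the OMV libraries correlated with Pearson r = 0.933 and Spearman rho = 0.911. The cell library correlated with them at Pearson r = 0.450 (named UC) and 0.488 (named qEV), or 0.662 and 0.739 over the 1189 protein-coding genes. With 1 library per isolation method and conflicting labels, these differences have no replicate check and compare the libraries, not the methods. On lp54, 40 of the 52 genes tested were higher in both OMV libraries than in cells and 10 were at least 8-fold higher in both, while 5 were lower in both, namely ospA, dbpB, lp6.6, BB_A64 and BB_A65, chosen after their values were seen.

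**Figure D4:**
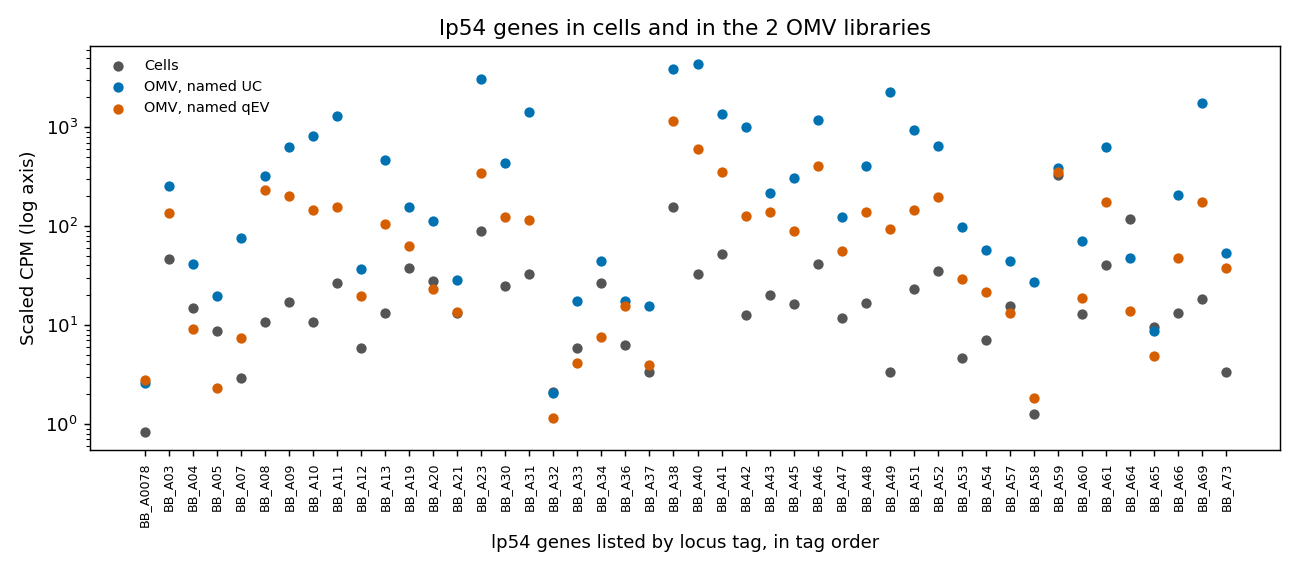
Scaled CPM (vertical log axis) of the lp54 genes listed by locus tag, in tag order, in the cell library and the OMV libraries named UC and qEV, with no error bars since each point is a single library. Genes listed by name, such as ospA and cspA, are not drawn, and BB_A49 stands 24.3-fold apart between the OMV libraries.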

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

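Tests of protein-coding genes alone, of edgeR's earlier quasi-likelihood method, of random lists of chromosomal or plasmid genes only, of list medians at the floor and of RNA classes without each OMV library were chosen only after the result was seen. All 32 named genes called by edgeR stayed called in every setting that gave them an adjusted p, and no named call turned direction. Of the 98 calls, 98 remained with DESeq2 size factors, total counts, TMM from protein-coding genes or no filter, 92 with TMM from chromosomal genes, 94 in DESeq2, 95 in limma-voom, 97 with the earlier method, 90 of 90 tested with at least 50 counts, 82 of 82 without the cp32 family and lp56, and 66 of 66 among protein-coding genes alone. The counts of 67 higher and 31 lower became 193 and 102 with DESeq2 size factors, 95 and 288 with total counts, 181 and 86 with TMM from protein-coding genes, 146 and 26 with TMM from chromosomal genes, 118 and 64 with no filter, 160 and 106 with at least 50 counts, 127 and 42 in the DESeq2 Wald test, 108 and 73 in limma-voom, 152 and 92 without the cp32 family and lp56, 136 and 78 among protein-coding genes alone, and 76 and 41 with the earlier method. The cause was not tested. Without each OMV library in turn no test was possible, and 312 to 357 genes were at least 2-fold higher and 283 to 304 lower. The 261 and 216 genes at least 2-fold apart in both OMV libraries became 150 and 492 with total counts, and 112 were lower with TMM from chromosomal genes. The cell share of lp54 was 21.5% of protein-coding counts and 20.2% without the 10 most abundant genes, and the mean OMV share 33.1% and 12.7%. The shares of all plasmids were 30.5% and 28.8% in cells and 49.5% and 18.4% in OMVs, by construction of the denominator. Without each OMV library, the OMV shares of all counts ranged from 1.58% to 6.003% for lp54, 3.31% to 7.40% for plasmids, 30.0% to 60.9% for rRNA, 31.4% to 56.8% for tRNA and 7.74% to 13.2% for protein-coding genes. With total counts, the log2 fold change turned negative for ospB (-0.69), rpsG (-0.65), clpP (-0.38), BB_0712 (-0.20), BB_0420 (-0.82), erpO (-0.62) and ftsY (-0.74), as did the outer surface lipoprotein median (-0.66). With TMM from chromosomal genes it turned positive for BB_0034 (0.28), rplC (0.30), rplB (0.16) and 23S_rrlA (0.051), as did the uptake median (0.0025). In limma-voom it turned negative for ospB (-0.00178) and ftsY (-0.040), and without the cp32 family and lp56 positive for BB_0034 (0.035) and rplC (0.056). None of these genes had passed the test. Of the lists, 8 had a median below 0, and 7 to 9 across the scalings, prior counts and omissions. With at least 200 counts, 35 genes were at least 2-fold higher in the OMV library named qEV than in the one named UC, since fewer genes were counted. Counts per kb for RNA classes and random lists matched on gene length were not run, since no gene lengths were used here. No paired analysis was possible because the cell group held 1 library. Of the 32 tRNA genes, 8 had 0 cell counts and 11 had 1 to 3, so their folds rest on the floor or have wide intervals.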

Other observations

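The tests of short RNA loss, rRNA depletion, plasmid DNA (partial or whole) and shared expression level were chosen only after the result was seen, as were the genes named in the next paragraphs.

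Further single genes among the 31 called lower in the OMV libraries are listed here, with no test of shared function. They included murB at -2.65 ± 0.53 (log2 fold change ± SE, edgeR adjusted p = 0.0367) and BB_0201 at -2.30 ± 0.50 (0.0451). BB_0651 (yajC) was at -3.004 ± 0.55 (edgeR adjusted p = 0.0281). napA, whose product binds metals and is known to activate neutrophils, was at -3.45 ± 0.69 (edgeR adjusted p = 0.0367), with 4297 counts in cells and 197 and 977 in the OMV libraries named UC and qEV. The genes rpiA and apt were at -3.28 ± 0.57 (edgeR adjusted p = 0.0220) and -3.54 ± 0.60 (0.0217), the ribosome recycling factor frr at -2.31 ± 0.50 (0.0453) and the glycine betaine transporter gene BB_0144 at -2.83 ± 0.54 (0.0305).

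Some plasmids were close to absent from all 3 libraries. In the cell library and the OMV libraries named UC and qEV, lp25 had 1, 5 and 22 counts, lp38 had 0, 13 and 15, lp28-4 had 9, 28 and 43, lp21 had 10, 4 and 21, cp9 had 8, 3 and 23, and lp5 had 7, 2 and 12. The lp54 porin gene osm28 had a scaled CPM of 223 in cells against 3871 and 878 in the OMV libraries named UC and qEV, and did not pass the test (log2 fold change 3.41 ± 1.15, edgeR adjusted p = 0.101). The gene of outer surface protein C (BB_B19), on cp26, had a scaled CPM of 16.7 in cells and 11.4 and 31.3 in the OMV libraries, and did not pass either (edgeR adjusted p = 0.749).

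The first pattern weighed was the tRNA share, which was far higher in both OMV libraries than in cells. Stronger removal of rRNA alone from the cell library would leave the ratio of tRNA to protein-coding counts as it is. That ratio was 4986-fold and 5311-fold higher in the OMV libraries than in cells, which argues against removal of rRNA alone. A depletion step that also lost tRNA-sized RNA is not covered by this ratio. Loss of short RNA from the cell library would also lower the short 5S rRNA in cells, and the ratio of 5S to 23S was a mean of 2.46-fold higher in the OMV libraries (2.19 in the one named qEV and 2.73 in the one named UC), but that of 5S to 16S was lower, at 0.147 and 0.135 against 0.195 in cells. The rRNA ratios thus went both ways and cover no RNA as short as tRNA, so a loss of tRNA-sized RNA alone and a higher tRNA content of OMVs cannot be told apart. A difference between OMVs and cells stays open and untested.

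The second pattern was the higher level of lp54 genes in the OMV libraries. Low cell counts drifting upward would raise chromosomal genes of the same cell level alike, but the lp54 median exceeded that of matched chromosomal sets by 3.14 (2.74 to 3.49) on the log2 scale, 2.93 against -0.20. Evenly covering plasmid DNA as the whole source would raise genes by their length, but the 90th percentile of the rise over cells was 58.5-fold (bootstrap interval 17.001 to 127) the 10th percentile of the total level in the library named qEV and 108-fold in the one named UC, above the 10-fold range allowed for gene lengths, which were not used here. DNA as part of the source could narrow the spread over genes, and the SD was 0.162 (bootstrap interval -0.43 to 0.93) higher in the OMV libraries than in cells, an interval on both sides of 0, so such a part and RNA alone cannot be told apart. Uneven DNA and a selective presence of lp54 transcripts in OMVs stay open and untested. Any difference in preparation between the cell and OMV libraries, such as unequal depletion, cannot be separated from the source of the RNA here.

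The final pattern was that neighbouring chromosomal genes had related fold changes, as in the run from BB_0240 to BB_0243. The correlation of log2 differences was 0.237 between adjacent locus numbers over 430 pairs of 573 genes, which are not independent replicates. Reads over the border of adjacent genes would not reach genes 3 locus numbers apart, where the correlation was still 0.168 (permutation range -0.0997 to 0.0971). A shared expression level of neighbours, as measured in the single cell library, did not account for all of it. After regression on cell log2 CPM, the correlation between adjacent genes fell from 0.237 to 0.140 (permutation range -0.0942 to 0.0939). A partial account by expression level stays open. The correlation was 0.0015 at 20 locus numbers. A candidate explanation is that genes transcribed together share their distribution. This hypothesis arose from the same data and was not tested, since no record of which genes are transcribed together was used here.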
